A study of Mus musculus with 10 samples.

How the data were processed

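RNA from mouse testis, strain C57BL/6, was sequenced at postnatal day 4 (P4) and postnatal day 7 (P7) from wild-type animals (WT) and from animals labelled as a conditional knockout of Lsm7 (cKO). The genotype label of the cKO samples is Lsm7-flfl-stra8. The labels name testis as the tissue and germ cell as the cell type, and the protocol describes extraction of total RNA from testis with TRIzol and TruSeq libraries, with no sorting step. The 10 libraries fell into 4 groups by their titles, with 2 WT and 3 cKO libraries at each stage. The labels state neither separate animals nor litters, dates or batches, so the p-values measure the spread between these samples, which may be technical.

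The authors deposited a single table of raw read counts per gene, as the file header and the whole-number values show, with gene coordinates and exon lengths. Per the submitters' processing notes, the tools were FastQC 0.12.1, MultiQC 1.14, Trim Galore 0.6.10, STAR 2.7.11a, SAMtools 1.6, featureCounts and Subread 2.0.6, and the build was GRCm38 (mm10). The strand setting and the handling of reads with several matches are not given in the sources used here. Counts of multicopy genes (histones, ribosomal proteins, Rn45s) and of overlapping or antisense genes are therefore uncertain. The table held 25239 genes, of which 3425 had no read in any library, and no gene of the mitochondrial chromosome. Most low counts were even numbers (67.8% to 80% of counts under 50), as when both mates of a pair are counted, so counting noise was taken as up to 1.93 times that of independent reads. Totals ran from 28.8 to 41.8 M reads per library. Floors cover counting error only, and bootstrap intervals the spread between genes of a list.

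Replicates were compared before averaging. The chi-square per degree of freedom over genes was 1.98 for the pair of P7 WT libraries, close to the 1.93 that paired mates alone give, against 23.5 to 122.9 for the other same-group pairs. The P7 WT libraries thus differed by about the sampling noise and were summed and counted as 1 sample. This departs from the design fixed before the data were examined, which had 10 libraries as separate samples. That fit is given as an alternative. The fit used here had 9 samples and 5 residual degrees of freedom, and the lone P7 WT sample was assumed to vary like the other groups.

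Counts were scaled with TMM factors, filtered with filterByExpr defaults (18419 genes kept) and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, 1 mean per group). P-values were two-sided and adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The common biological coefficient of variation was 0.228. Standard errors (SE) are the log2 fold change divided by the square root of F. The comparisons were cKO against WT at each stage, P7 against P4 in each genotype, and the genotype by stage interaction. CPM values are counts scaled to 1 M reads per library with TMM factors, as mean ± SD over samples. A group with no read was set at a floor of 3 counts over its summed libraries. Folds at that floor are lower bounds for independent counts only. As both mates of a pair seem to be counted, the fold that can be assured is smaller.

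Gene lists (26, written before the data were examined) were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Lists with fewer than 5 tested members (erythroid cell, scaRNA genes, mitochondrially encoded) were not tested, which left 23. The directional test fry was run beside camera. Counts of list members are given over all genes tested and adjusted over the list alone. Genes named in the text follow a rule also fixed beforehand. It took the 10 highest and the 10 lowest fold changes among genes past the threshold with an average log2 CPM of 1 or more, an assigned symbol and no overlap between the groups. It added up to 4 members with the smallest p of each called list and 13 genes named whatever their result. A gene that met this rule is not reported here. Genes outside this rule are marked as chosen after their values were seen.

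The simulated test of the scripts changed 200 of 18419 genes by a log2 fold change of 1 or 2 (100 each). For cKO against WT, 45 of 100 and 97 of 100 were recovered at P4, and 9 of 100 and 90 of 100 at P7. For P7 against P4, 12 and 91 of 100 were recovered in WT, and 67 and 100 of 100 in cKO. Between the genotypes, false calls were 11 of 153 calls at P4 and 10 of 109 at P7. Between the stages they were 10 of 113 calls in WT and 14 of 181 in cKO. In each comparison the share of false calls lay above the threshold set for adjusted p-values.

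Alternatives fixed beforehand were edgeR's RLE factors, library totals without a composition factor, no filter, a stricter filter (minimum count 50), DESeq2 1.42.0, limma-voom, a fit of the compared libraries alone, the replicate number as a block (over all groups or within stage), a fold threshold, Spearman correlation, and leaving out each library. The 10-library fit was the design fixed beforehand and became an alternative once the P7 WT libraries had been summed. Alternatives chosen after seeing the data were offsets for gene length and GC content, a fit without the P7 WT libraries, and correlations limited to genes with an average log2 CPM of 1 or more. The offsets were loess trends (span 0.3) of each sample's deviation from the gene mean on exon length and transcript GC, for which 99.0% of tested genes had a value. With offsets, lists were tested by camera on corrected log2 CPM, and where the text says so on counts; the latter, and the estimated correlation with offsets, were also chosen after seeing the data. Sequencing of immunoprecipitated RNA, which the series design also names, was not analysed here. Figures were drawn with matplotlib 3.10.9.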

Results

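Gene expression was measured by RNA-seq in the mouse testis at P4 and P7, days around which spermatogonia, the stem and progenitor cells of the male germ line, begin to differentiate. The series design sets WT against Lsm7-null germ cells. Lsm7 encodes a subunit of the LSm ring that binds U6 small nuclear RNA and takes part in messenger RNA decay. At P4, the WT libraries held 28.8 and 33.0 M reads and the cKO libraries 36.2, 31.4 and 41.8 M. At P7, the WT libraries held 28.9 and 30.0 M and the cKO libraries 30.9, 37.9 and 39.3 M. The P7 WT libraries differed by about the sampling noise (chi-square per degree of freedom 1.98, against 1.93 from paired mates alone) and were counted as 1 sample, so that WT contributed 2 samples at P4 and 1 at P7, and cKO 3 at each stage.

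Lsm7 (chromosome 10, 80852825 to 80855209, GRCm38) was read at 36.2 and 25.7 CPM in the P4 WT samples and at 44.9, 50.5 and 43.6 CPM in the P4 libraries labelled cKO. At P7 it was read at 33.3 CPM in the WT sample and at 45.2, 26.0 and 20.3 CPM in the libraries labelled cKO. The log2 fold change in the libraries labelled cKO was 0.58 at P4 (SE 0.30, edgeR adjusted p = 0.215) and -0.13 at P7 (SE 0.37, adjusted p = 0.835). Leaving out P7 cKO library 1 brought the P4 difference past the threshold (log2 0.58, adjusted p = 0.0361), and leaving out P7 cKO library 3 turned the sign at P7 (log2 0.10). With offsets for gene length and GC content the values were 0.25 at P4 (adjusted p = 0.433) and -1.02 at P7 (adjusted p = 0.141). Over all alternatives the adjusted p ran from 0.0361 to 0.556 at P4 and from 0.1196 to 0.983 at P7. A lower Lsm7 level was therefore not detected in the libraries labelled cKO, while at P7 the size of the change rested on that correction. The count table does not separate exons, so reads outside a deleted part cannot be told from reads of an intact gene. The label Lsm7-flfl-stra8 names Stra8, which was read at 4.63 and 3.18 CPM in the P4 WT samples. If only cells expressing Stra8 lost Lsm7, its level in unsorted testis could stay unchanged, which was not tested. The Lsm7 level thus neither backs nor contradicts the genotype labels, and the directions below are those of libraries so labelled.

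**Figure D1:**
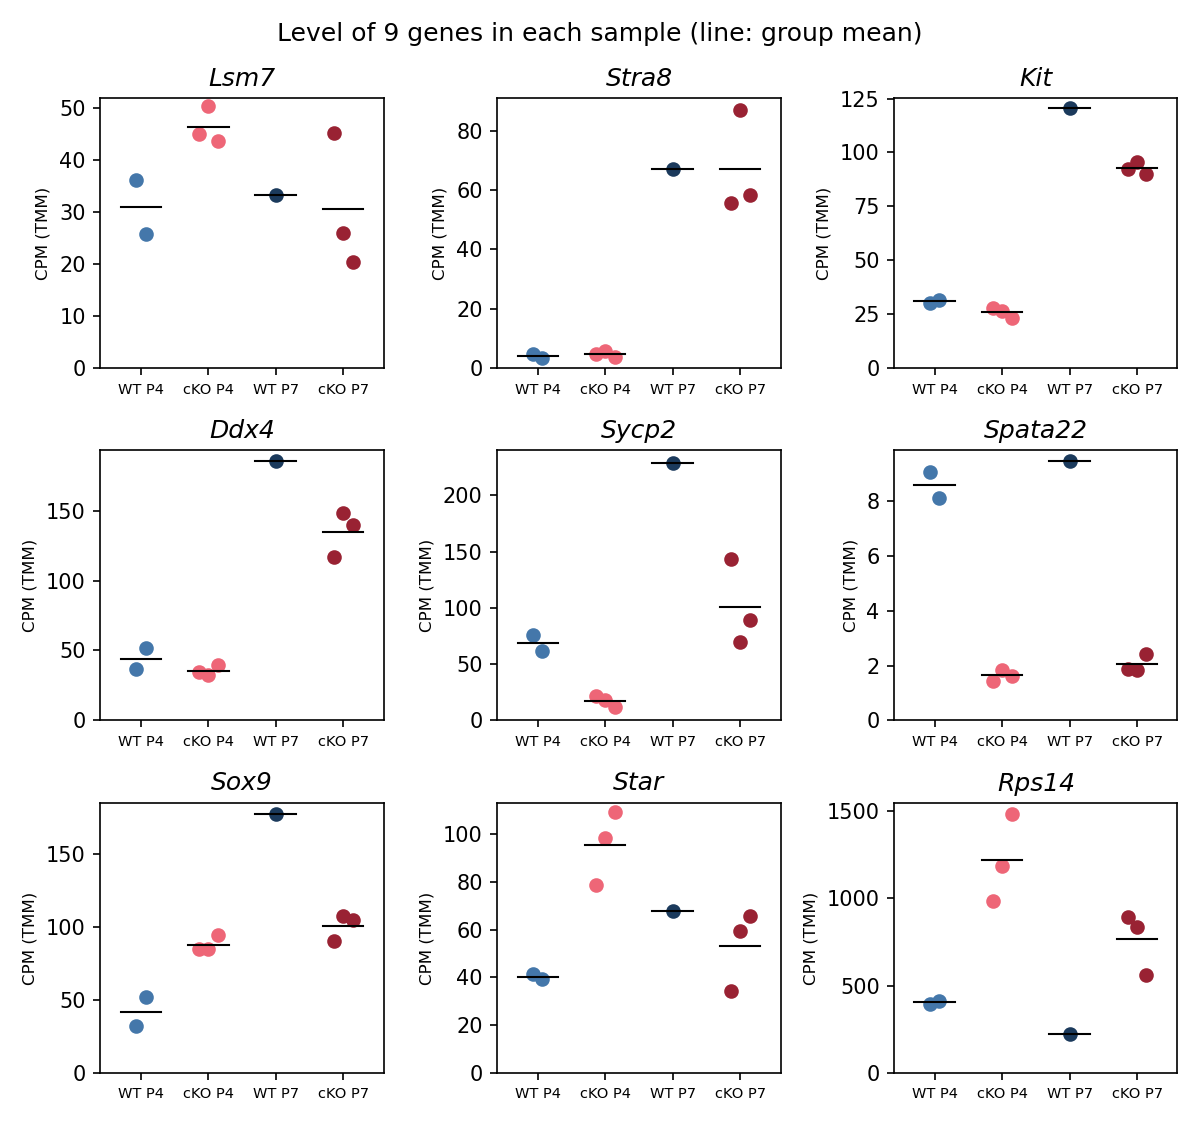
TMM-scaled level (CPM, vertical axis from 0) of 9 genes in each sample of the 4 groups (horizontal axis); points are samples and lines are group means. Lsm7 lies at 43.6 to 50.5 CPM in the P4 cKO samples and at 25.7 and 36.2 in WT, and Stra8 lies at 67.2 CPM in the P7 WT sample against 3.18 and 4.63 in P4 WT.

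The first question was which genes differ between the genotypes at P4. Genes of meiotic entry and prophase were lower in the libraries labelled cKO. Sycp2, a synaptonemal complex protein, fell by 1.97 on the log2 scale (SE 0.30, adjusted p = 0.0122, n = 3 and 2). Spo11, which makes the meiotic DNA breaks, fell by 1.94 (SE 0.30, adjusted p = 0.0122), Msh4, a crossover factor, fell by 1.95 (SE 0.39, adjusted p = 0.0209), and Terb1, which tethers meiotic telomeres, fell by 1.91 (SE 0.31, adjusted p = 0.0122). Of the 27 list members, 10 fell and 0 rose over all genes tested, and 17 fell and 1 rose adjusted over the list alone. The list median was -0.68 (camera adjusted p = 3.46e-07), and the adjusted p = 0.235 with an estimated correlation. Transcripts of spermatids, cells that a testis of this age should lack, moved the same way. A list of 20 such genes, written after the libraries were first examined, summed to 20.6, 24.8 and 19.6 RPM (reads per library scaled to 1 M) in the libraries labelled cKO against 36.2 and 27.3 RPM in WT. Smcp had 12, 22 and 14 reads against 64 and 58, Akap4 had 10, 26 and 30 against 78 and 72, Spz1 had 10, 20 and 18 against 60 and 42, and Cabs1 had 4, 8 and 2 against 26 and 24. Gapdhs ran the other way (319, 229 and 289 against 125 and 183). No clear fall was seen for others, among them Prm1 (10, 34 and 35 against 30 and 32) and Tnp2 (46, 39 and 18 against 34 and 33). The same held for Tssk6 (27, 29 and 43 against 26 and 9) and Spaca1 (77, 59 and 117 against 65 and 91). Reads of single genes are not scaled to library totals here, and the spermatid genes named were chosen after their values were seen. Of 21 pan-germ-cell genes, 3 fell (4 adjusted over the list alone). These were Mael (log2 -0.99, SE 0.18), Tdrd9 (-0.97, SE 0.21) and Tex15 (-1.05, SE 0.24), of which Mael and Tdrd9 belong to the piRNA pathway. The list median was -0.40 (camera adjusted p = 0.00291, and adjusted p = 0.394 with an estimated correlation). The spermatogonial genes Gfra1 (0.46, adjusted p = 0.397), Zbtb16 (-0.03, adjusted p = 0.940), Id4 (-0.38, adjusted p = 0.293), Kit (-0.26, adjusted p = 0.276) and Stra8 (0.28, adjusted p = 0.534) did not pass. Neither did the germ cell genes Ddx4 (-0.32, adjusted p = 0.290), Dazl (-0.42, adjusted p = 0.282) and Sycp3 (-0.64, adjusted p = 0.128). Sycp3 did pass in a fit of the P4 libraries alone (-0.65, adjusted p = 0.0386) and without P7 cKO library 1 (-0.64, adjusted p = 0.0131), in a range over alternatives from 0.0131 to 0.441.

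Lists of Leydig, Sertoli, stromal and macrophage markers were higher at P4 in the libraries labelled cKO, though single members ran the other way. Star, which carries cholesterol into mitochondria for steroid synthesis, rose by 1.24 on the log2 scale (SE 0.26, adjusted p = 0.0224), from 40.3 to 95.3 CPM. Fdx1, the electron donor of steroidogenic enzymes, rose by 1.36 (SE 0.25, adjusted p = 0.0168), and Insl3, a Leydig cell peptide hormone, rose by 3.65 (SE 0.85, adjusted p = 0.0331). In all, 3 of 12 Leydig cell genes rose (6 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 0.00347. Hsd17b3 of that list was lower, at 470.0, 480.4 and 418.8 CPM in the libraries labelled cKO against 889.3 and 582.9 CPM in WT. Of 18 Sertoli cell genes, 6 rose, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00608). Among these were Sox9, the Sertoli cell determinant (1.06, SE 0.21), Clu (0.98), Aard (0.92) and Amh (0.88), the anti-Müllerian hormone. Of 14 peritubular and stromal genes, 3 rose (3 adjusted over the list alone), the contractile genes Cnn1 (1.18), Tagln (1.13) and Des (0.75), with a camera adjusted p of 0.0132. Mylk of that list was lower, at 377.6, 455.6 and 412.2 CPM in the libraries labelled cKO against 577.5 and 567.9 CPM in WT. Of 12 macrophage genes, 3 rose (5 adjusted over the list alone), Lyz2 (1.74), C1qa (1.10) and C1qb (0.97), with a camera adjusted p of 0.0418. Star did not pass without P4 WT library 1 (1.28, adjusted p = 0.216), P4 WT library 2 (1.21, 0.0698), P4 cKO library 2 (1.21, 0.0735) or P4 cKO library 3 (1.12, 0.0826), and passed in 18 of 22 alternatives (range 3.42e-04 to 0.216). Sox9 did not pass without P4 WT library 1 (0.76, 0.216), P4 cKO library 2 (1.08, 0.0667) or P4 cKO library 3 (1.00, 0.0720), and passed in 19 of 22 (range 2.00e-04 to 0.216). With an estimated correlation no list of these cell types passed (Leydig cell adjusted p = 0.260, Sertoli cell 0.394, stromal 0.531, macrophage 0.531).

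Ribosomal protein genes were higher at P4 in the libraries labelled cKO. Of 84, 47 rose and 0 fell (67 rose adjusted over the list alone). The median log2 fold change was 0.83 (camera adjusted p = 7.40e-32, and adjusted p = 0.260 with an estimated correlation). Rps14 rose by 1.59 (SE 0.25), Rps19 by 1.46 (SE 0.23) and Rpl13 by 1.36 (SE 0.19), and Rplp1, of the ribosomal stalk, also passed (SE 0.22, adjusted p = 0.0114). Of 48 core spliceosome genes, 6 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 1.88e-04, and adjusted p = 0.260 with an estimated correlation). Snrpb, a core Sm protein, rose by 1.86 (SE 0.43), Sf3b5 by 0.96 and the splicing factor Prpf19 by 0.85, while Sf3b1 fell by 0.85 (SE 0.19). Among 13 LSm genes, 1 rose (2 adjusted over the list alone), Lsm4 (0.95, SE 0.26); the list median was 0.45 (camera adjusted p = 0.0418, and adjusted p = 0.394 with an estimated correlation). Of 17 genes of the integrated stress response, 2 rose (2 adjusted over the list alone), Phgdh (1.01) of serine synthesis and the transcription factor Cebpb (1.73), with a camera adjusted p of 0.0418 (0.0573 on log2 CPM, which did not pass) and an adjusted p = 0.260 with an estimated correlation. Psat1 of the stress response list was lower, at 76.7, 81.9 and 84.8 CPM in the libraries labelled cKO against 114.2 and 93.5 CPM in WT. Of 18 interferon response genes, 5 fell and 1 rose, over all genes and adjusted over the list alone. Oasl2 fell by 1.44 (SE 0.20), the RNA sensor genes Ifih1 (-1.04) and Ddx58 (-0.97) fell as well, and Bst2 rose by 0.88; camera gave an adjusted p of 0.00438, and the adjusted p = 0.260 with an estimated correlation. Of 51 replication-dependent histone genes, 1 rose (1 adjusted over the list alone), H1f2 (2.03, SE 0.42). Their median was 1.32, or 0.92 with the 9 members lacking reads in a group held at their bound (camera adjusted p = 0.00608, and adjusted p = 0.553 with an estimated correlation).

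Among single genes that met the naming rule, the highest increases at P4, beside Insl3, were those of the ribosomal RNA precursor Rn45s (2.46, SE 0.36), the kinase Jak3 (2.44, SE 0.60), Rnaset2b (2.24, SE 0.33), Eps8l1 (2.12, SE 0.53), Itm2c (2.06), Nxph3 (2.05), H1f2, Wfikkn2 (1.97) and the phosphatase Dusp9 (1.93). The lowest were the adenylate kinase Ak9 (-3.00, SE 0.32), Gdap1 (-2.97, SE 0.41), Cnpy1 (-2.89), Efcab3 (-2.62), the meiotic recombination genes Spata22 (-2.39, SE 0.26) and Shoc1 (-2.35, SE 0.24), the noncoding RNA Rmst (-2.21), Dscaml1 (-2.16), Abca16 (-2.14) and Zfp54 (-2.13). Some genes that this rule leaves out for lack of an assigned symbol changed more, chosen after their values were seen. AI506816 (7.53) and 4930413G21Rik (3.07) rose, and Gm8615 (-7.15) fell. Spata22 was read at 9.07 and 8.11 CPM in WT and at 1.45, 1.85 and 1.63 CPM in the libraries labelled cKO. Rn45s took 0.0983% and 0.0782% of reads in P4 WT libraries and 0.316%, 0.649% and 0.337% in the libraries labelled cKO.

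In all, 891 genes rose and 760 fell at P4 by edgeR's test, of 18419. The count rested on single libraries. It was 2 without P4 WT library 1, 816 without P4 WT library 2, and 570, 13 and 11 without P4 cKO libraries 1, 2 and 3, while it was 4157 without P7 cKO library 1, a library outside the comparison. P7 cKO library 1 entered this comparison through the estimate of the spread, which all groups shared. Its chi-square per degree of freedom was 117.3 and 122.9 against the other P7 cKO libraries, and 23.5 between those. With library totals as the scale, which moved the median of all genes from 0.00 to -0.16, 528 rose and 1544 fell. With offsets for length and GC content, 288 rose and 282 fell, 491 of them shared with the calls without offsets. The median absolute log2 fold change of the called genes went from 0.97 (median SE 0.216) to 0.82 (median SE 0.218). The meiotic list median was then -0.64, that of the ribosomal genes 0.65, and 7 of the 12 called lists passed. The Sertoli cell (median 0.39 without and 0.33 with offsets, adjusted p = 0.0786 with offsets), macrophage (0.60 and 0.44, 0.146), LSm (0.45 and 0.25, 0.0543), stress response (0.24 and 0.22, 0.1995) and histone lists (1.32 and 0.76, 0.1995) did not. With offsets and an estimated correlation no list passed (smallest adjusted p 0.349). Not called at P4 were the lists of undifferentiated spermatogonia (median 0.07, or -0.08 with library totals), differentiating spermatogonia (-0.25), endothelial cells (0.25), the minor spliceosome (0.05, or -0.11 with library totals), Cajal bodies (0.03, or -0.13), snoRNA hosts (0.34), messenger RNA decay (-0.19), p53 targets (0.19), the cell cycle (0.10, or -0.06), retinoic acid response (0.18) and snoRNA genes (0.14, or -0.01). The p53 targets Cdkn1a (0.47, adjusted p = 0.329) and Mdm2 (-0.23, adjusted p = 0.364) did not pass. The erythroid list had a median of 2.45 over 3 tested genes and the scaRNA list -0.66 over 2, both untested.

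**Figure D2:**
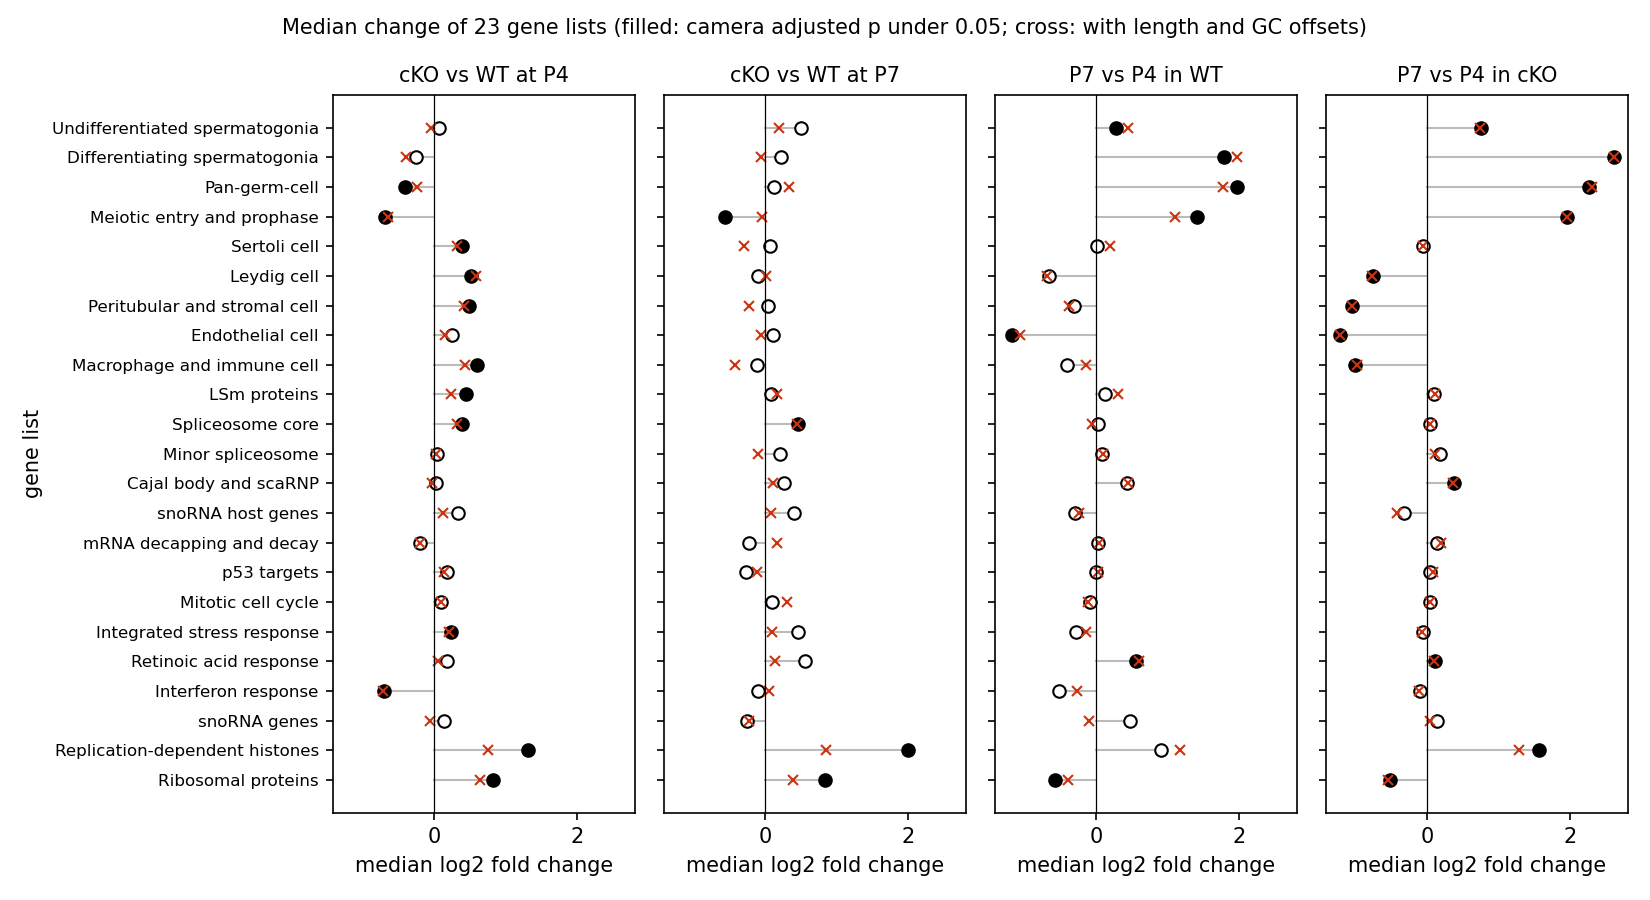
Median log2 fold change (horizontal axis) of 23 gene lists (vertical axis) in 4 comparisons; filled points passed camera at an adjusted p under 0.05 with the preset correlation, and crosses give the median with length and GC offsets. In cKO against WT at P4, the meiotic list lies at -0.68 and the ribosomal list at 0.83; with library totals as the scale the open points near 0 change sign (undifferentiated spermatogonia 0.07 to -0.08).

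At P7 the same question rested on 1 WT sample against 3 labelled cKO. Spata22 fell by 2.20 on the log2 scale (SE 0.30, adjusted p = 0.00642) and Meioc, a regulator of meiotic entry, fell by 2.23 (SE 0.27, adjusted p = 0.00642), from 42.3 CPM to 8.20, 9.55 and 9.34 CPM. Of 27 meiotic genes, 5 fell and 2 rose (6 and 2 adjusted over the list alone), among them Sycp1 (-1.65), Ythdc2 (-1.60) and Hormad1 (-1.42). With length and GC offsets none of the genes just named passed, at -1.73 for Spata22 (adjusted p = 0.0850), -1.17 for Meioc (0.113), -0.42 for Sycp1 (0.623), -0.77 for Ythdc2 (0.315) and -0.48 for Hormad1 (0.471). The median was -0.55 (camera adjusted p = 0.00830, and adjusted p = 0.491 with an estimated correlation). With those offsets it was -0.04. Spermatid transcripts ran opposite to this list at P7, at 9.56 and 8.85 RPM in the WT libraries and 52.6, 26.97 and 23.1 RPM in the libraries labelled cKO. Dazl, an RNA-binding protein of germ cells, fell by 1.11 (SE 0.30, adjusted p = 0.0281), and its value with offsets was -0.09 (adjusted p = 0.919). Dazl did not pass in a fit of the P7 libraries alone (-1.14, adjusted p = 0.0663) or without P7 cKO library 2 (-1.08, adjusted p = 0.0781), in a range over alternatives from 0.00221 to 0.919. Sox9 fell by 0.82 (SE 0.24, adjusted p = 0.0402), and its call rested on the setting. It passed in 14 of 21 alternatives (range 0.00238 to 0.224), and not with offsets (-0.66, adjusted p = 0.224), with library totals (-0.71, 0.0582) or in a fit of the P7 libraries alone (-0.85, 0.0776). Nor did Sox9 pass without P4 cKO library 1 (-0.81, 0.0542), P4 cKO library 2 (-0.81, 0.0650), P7 cKO library 2 (-0.86, 0.0800) or P7 cKO library 3 (-0.85, 0.0617). Stra8 (-0.01), Kit (-0.38), Gfra1 (0.50), Zbtb16 (0.19), Id4 (-0.25), Ddx4 (-0.46), Sycp3 (-0.79), Star (-0.35), Cdkn1a (0.35) and Mdm2 (-0.47) did not pass, and with offsets the values of Id4, Ddx4, Sycp3, Star and Cdkn1a changed sign. Mdm2 passed with 10 libraries (-0.45, edgeR adjusted p = 0.0242) and with the replicate number as a block (-0.44, 0.0367). Kit passed with 10 libraries (-0.36, 0.0484) and Ddx4 with the block (-0.50, 0.0328). These fits took the P7 WT libraries apart. Sycp3 passed without P7 cKO library 1 (-1.14, adjusted p = 0.00195) and with 10 libraries (-0.77, 0.0218), in a range from 0.00195 to 0.950.

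Ribosomal protein genes were again higher at P7, with 37 of 84 up and 0 down (52 up adjusted over the list alone), a median of 0.85 (0.39 with length and GC offsets) and a camera adjusted p of 2.17e-17 (adjusted p = 0.491 with an estimated correlation). Rpl29 rose by 1.84 (SE 0.24), Rps14 by 1.78 (SE 0.33), Rpl13 by 1.62 and Rpl18 by 1.44. Of 48 core spliceosome genes, 12 rose (14 adjusted over the list alone), among them Sf3b5 (1.37, SE 0.22), the U1 protein gene Snrnp70 (1.24), Sart1 (1.19) and Sart3 (0.94). Their median was 0.46, or 0.45 with offsets (camera adjusted p = 3.68e-04, and adjusted p = 0.491 with an estimated correlation). Of 51 histone genes, 3 rose (1 adjusted over the list alone). At the floor, H2ac13 was 32.2-fold higher and Hist1h2an 9.45-fold higher, since no read fell on them in the WT libraries, and H2bc11 rose by 5.42 (SE 1.67). P7 cKO sample 1 was the highest, with H2bc11 at 9.60 CPM against 1.26 and 0.778 in samples 2 and 3. There H2ac13 was at 3.16 CPM against 1.51 and 0.656, and Hist1h2an at 0.851 against 0.452 and 0.243. The histone median was 2.00, or 0.86 with offsets (camera adjusted p = 0.00477, and adjusted p = 0.918 with an estimated correlation).

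Not called at P7 were the lists of undifferentiated spermatogonia (median 0.50), differentiating spermatogonia (0.23), pan-germ-cell genes (0.12), Sertoli cells (0.07), Leydig cells (-0.09, or 0.01 with library totals), stromal cells (0.04), endothelial cells (0.12), macrophages (-0.11, or 3.14e-04 with library totals), LSm proteins (0.09), the minor spliceosome (0.21), Cajal bodies (0.27), snoRNA hosts (0.41), messenger RNA decay (-0.23), p53 targets (-0.26), the cell cycle (0.10), stress response (0.47), retinoic acid response (0.56), interferon response (-0.10, or 0.01 with library totals) and snoRNA genes (-0.25). The meiotic and histone lists no longer passed with length and GC offsets, while pan-germ-cell genes (0.34, camera adjusted p = 0.0183) and Sertoli cell genes (-0.29, adjusted p = 0.00120) did. Pan-germ-cell genes had an adjusted p = 0.963 with an estimated correlation without offsets and 0.901 with them, and Sertoli cell genes 0.920 and 0.866. The scaRNA list had a median of 1.15 over 2 tested genes.

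Among single genes that met the naming rule, Prm2, a sperm protamine, was 64.8-fold higher and H60b 14.7-fold higher at the floor in the libraries labelled cKO, with no read in P7 WT. Prm2 had 226, 74 and 84 reads in P7 cKO libraries 1, 2 and 3. H60b was read there at 0.0304, 1.005 and 1.12 CPM. Eps8l1 (3.42, SE 0.76), the sperm lactate dehydrogenase Ldhc (3.36, SE 0.96), Mylk2 (2.94), Erdr1 (2.91), Gsc (2.71), Rbmxl2 (2.55) and Lmtk3 (2.54) followed. The lowest, beside Spata22 and Meioc, were Alas2, the first enzyme of haem synthesis in red cells (-2.54, SE 0.40), Pde10a (-2.25), Lysmd3 (-2.24), Vnn1 (-2.22), Pcdhb18 (-2.21), Tbx22 (-2.20), Slc6a14 (-2.19) and Rmst (-2.18). The erythroid list had a median of -2.62 over 3 tested genes.

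By edgeR's test, 1338 genes rose and 1791 fell at P7. The fold changes followed transcript GC content (Spearman 0.653 across genes, which are not independent replicates), and the P7 WT libraries had the strongest GC trend of all. Only 2 genes passed with length and GC offsets, both lower in the libraries labelled cKO. They were Gm8615 (-6.32 with offsets, adjusted p = 0.00623) and the X-linked gene Zxda (-3.00 with offsets, adjusted p = 0.0180), named after their values were seen. The median absolute log2 fold change of the called genes went from 1.08 (median SE 0.255) to 0.40 (median SE 0.225), so the calls ended through smaller folds. The count was 0 by edgeR in a fit of the P7 libraries alone (4834 at an unadjusted p under 0.05, smallest adjusted p 0.0663; over all libraries DESeq2 called 4247 and limma-voom 3495). It was 961 without P7 cKO library 2, 4921 without P7 cKO library 1 and 2012 without P4 cKO library 2. With library totals as the scale, which put the median of all genes at 0.19 against 0.08, 1744 rose and 1402 fell.

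**Figure D3:**
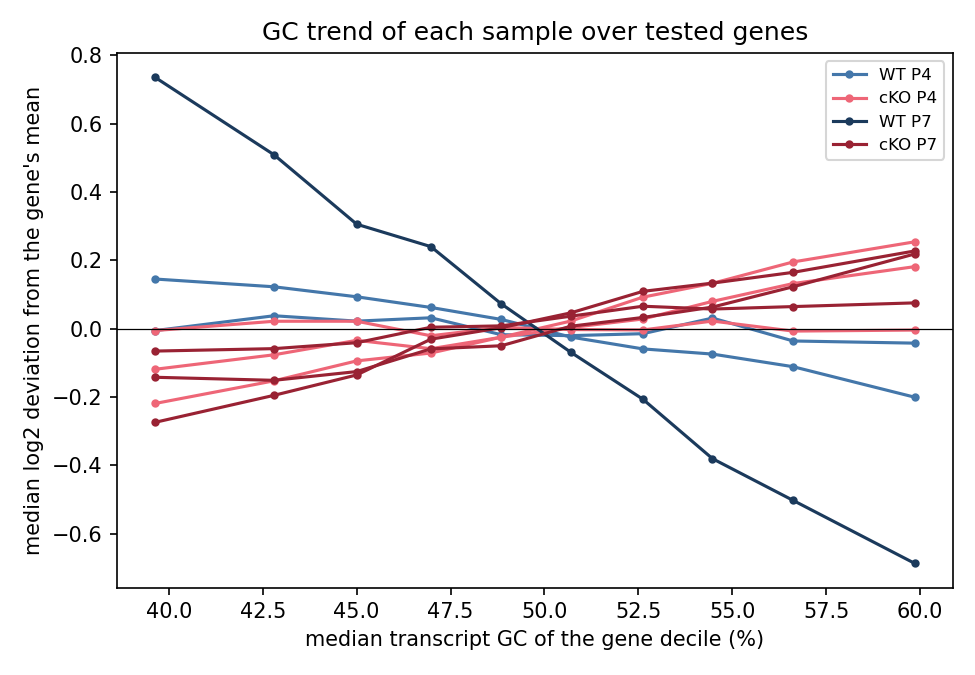
Median log2 deviation of genes from their mean over samples (vertical axis) in 10 bins of transcript GC content (horizontal axis, percent), 1 line per sample, coloured by group. The P7 WT sample runs from 0.74 in the bin at 39.6% GC to -0.69 in the bin at 59.9% GC.

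The fold changes of the genotypes at P4 and at P7, which share no library, were compared across genes. Pearson's r was -0.00 over all 18419 genes (Spearman 0.131) and 0.277 over 13576 genes with an average log2 CPM of 1 or more. Genes that rose at both stages numbered 329, against 64.7 by chance, and genes that fell at both numbered 221, against 73.9. Spata22, Rmst, Eps8l1, Rps14, Rpl13 and Sf3b5 were among those shared, and 10 genes moved in opposite directions. These fold changes also followed transcript GC content (Spearman 0.224 at P4 and 0.653 at P7). With length and GC offsets only 2 genes passed at P7, and the correlation was -0.12 over all genes and 0.0779 over the genes with an average log2 CPM of 1 or more. The interaction called 0 genes by edgeR's test, with a smallest adjusted p of 0.0626, while 4619 genes had an unadjusted p under 0.05. DESeq2 called 1665 and limma-voom 0, and edgeR called 716 without P4 WT library 2, 1455 without P7 cKO library 1 and 1 without P7 cKO library 2. No list passed without offsets, and 4 passed without P4 cKO library 1. With length and GC offsets, 8 of 23 lists passed at the preset correlation, namely pan-germ-cell (0.63, adjusted p = 7.63e-04), meiotic (0.57) and interferon genes (0.56) upwards, and Sertoli cell (-0.61, adjusted p = 7.63e-04), Leydig cell (-0.65), stromal (-0.85), macrophage (-0.77) and ribosomal genes (-0.17) downwards. With offsets and an estimated correlation none passed (smallest adjusted p 0.639). With the offsets on counts rather than on log2 CPM, 7 passed at the preset correlation, and interferon genes did not (adjusted p = 0.0746). The interaction was -1.88 for Sox9 (SE 0.32, adjusted p = 0.0626), -1.59 for Star (SE 0.40, adjusted p = 0.0715) and -0.71 for Lsm7 (SE 0.47, adjusted p = 0.354). Whether these passed depended on the setting. Sox9 and Star passed with DESeq2 (adjusted p = 2.33e-04 and 0.0119), in edgeR without a filter (0.0319 and 0.0416), with 10 libraries (0.0115 and 0.0162) and in edgeR without P7 cKO library 1 (0.0102 and 0.0176), and Sox9 also without P4 WT library 2 (0.0382). Neither passed with limma-voom or with length and GC offsets, and over all alternatives the highest adjusted p was 0.285 for Sox9 and 0.287 for Star. Without P7 cKO library 1 the interaction of Lsm7 was -1.11 (adjusted p = 0.0406, range over alternatives 0.0406 to 0.569).

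Between P4 and P7 in WT, genes of germ cells rose. The later stage was 1 sample, so stage and anything particular to the P7 WT libraries coincide here. The fold changes followed transcript GC content (Spearman -0.340), and Gpx5 (550 and 596 reads in P7 WT, 12 to 122 in the others) and Prm2 (no read in P7 WT) parted those libraries from all others. Stra8, a retinoic acid target needed for meiotic entry, rose by 4.11 on the log2 scale (SE 0.35, adjusted p = 1.65e-04, n = 1 and 2), and Kit, a receptor of differentiating spermatogonia, rose by 1.96 (SE 0.20, adjusted p = 4.05e-04). Zbtb16, a transcription factor of spermatogonial progenitors, rose by 3.04 (SE 0.31), Dazl by 3.25, Ddx4 by 2.07 and Sycp3 by 2.37. The Sertoli cell gene Sox9 rose by 2.08. Of 18 genes of differentiating spermatogonia, 12 rose (13 adjusted over the list alone), with Sohlh2 (2.72) and Dnmt3b (1.54) among them. Of 21 pan-germ-cell genes, 17 rose (18 adjusted over the list alone), with Mageb4 (2.74), Rnf17 (2.46) and Tdrd1 (2.26). Of 27 meiotic genes, 18 rose (19 adjusted over the list alone), with Tex11 (3.99), Meioc (2.87), Sycp1 (2.85) and Smc1b (2.22). Of 27 genes of undifferentiated spermatogonia, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Neurog3 (4.99), Lin28a (3.52) and Foxo1 (1.74).

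Of 18 retinoic acid response genes, 6 rose and 3 fell in WT (7 and 3 adjusted over the list alone), with Crabp1 (2.67), Rbp4 (1.84) and Rec8 (1.47). Of 10 endothelial genes, 7 fell (9 adjusted over the list alone), Tie1 (-2.30), Vwf (-1.72), Egfl7 (-1.47) and Pecam1 (-1.19) among them. Of 84 ribosomal protein genes, 17 fell and 3 rose (18 and 3 adjusted over the list alone). Rpl36 fell by 1.56 and Rpl29 fell by 1.41, while Rpl10l (1.83) and Rpl39l (1.34), paralogs expressed in the male germ line, rose. These 7 lists passed camera at adjusted p-values from 1.10e-21 to 0.0445 on counts. On log2 CPM, undifferentiated spermatogonia (adjusted p = 0.0678) and retinoic acid response (0.159) did not pass without offsets. With an estimated correlation the pan-germ-cell and meiotic lists passed (adjusted p = 0.0486 for each), and the others did not (adjusted p = 0.0615 for differentiating, 0.460 for undifferentiated, 0.229 for retinoic acid, 0.261 for endothelial and 0.606 for ribosomal genes). With offsets and an estimated correlation no list passed on log2 CPM (smallest adjusted p 0.123), and on counts differentiating spermatogonia did (adjusted p = 0.0359). The highest single genes under the naming rule were Tbx22 (5.87), Btnl10 (5.71), Neurog3, Rspo2 (4.91), Gpx5 (4.42), Kbtbd8 (4.39), Lpar3 (4.32), Mei4 (4.25), Usp26 (4.24) and Dmrtb1 (4.23). The lowest were H60b and Prm2 (84.2-fold and 34.2-fold lower at the floor, with no read at P7), Pnmt, which makes adrenaline (-6.93), Cnga1 (-6.47), Brinp3 (-6.15), the chemokine Ccl17 (-5.81), Mylk2 (-5.41), Lamp5 (-5.36), Pdyn (-5.33) and Gsc (-5.21). Lsm7 (0.11), Gfra1 (0.12), Id4 (-0.19), Star (0.75), Cdkn1a (-0.09) and Mdm2 (0.31) did not pass, but Star did without P7 cKO library 1 (0.75, adjusted p = 0.0162, range over alternatives 0.0145 to 0.262). In all 2179 genes rose and 1837 fell. The count was 1187 without P4 WT library 1 and 6315 without P7 cKO library 1, and 3059 with offsets (2403 shared).

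Not called in WT were the lists of Sertoli cells (median 0.02, or -0.07 with library totals), Leydig cells (-0.65), stromal cells (-0.31), macrophages (-0.40), LSm proteins (0.12), the core spliceosome (0.04, or -0.05), the minor spliceosome (0.08), Cajal bodies (0.44), snoRNA hosts (-0.28), messenger RNA decay (0.04, or -0.05), p53 targets (-0.00), the cell cycle (-0.08), stress response (-0.28), interferon response (-0.51), snoRNA genes (0.48) and histones (0.92, or 0.58 with 11 members at their bound). On log2 CPM without offsets, Cajal bodies (adjusted p = 0.0388) and snoRNA genes (0.0387, and adjusted p = 0.573 with an estimated correlation on counts) passed. With offsets, the Sertoli cell, Cajal body and histone lists passed as well (adjusted p = 0.0341, 0.0104 and 0.00548). These 3 had an adjusted p of 0.606, 0.229 and 0.793 with an estimated correlation without offsets, and of 0.602, 0.154 and 0.602 with them. The erythroid and scaRNA lists had medians of 1.56 and -0.60, untested. Library totals moved the median of all genes from -0.03 to -0.11.

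Germ cell genes rose between the stages in the libraries labelled cKO as well. Stra8 rose by 3.82 (SE 0.26, adjusted p = 7.73e-06, n = 3 and 3), Kit by 1.85 (SE 0.14, adjusted p = 1.70e-05), Zbtb16 by 3.26, Dazl by 2.55, Ddx4 by 1.93 and Sycp3 by 2.22. All 21 tested pan-germ-cell genes rose (21 adjusted over the list alone), with Mageb4 (2.85), Mov10l1 (2.50), Tdrd1 (2.33) and Mael (2.24). Of 27 meiotic genes, 23 rose (24 adjusted over the list alone), with Ankrd31 (3.33), Syce1 (2.60), Smc1b (2.41) and Stag3 (2.22). Of 18 genes of differentiating spermatogonia, 15 rose and 1 fell (15 and 2 adjusted over the list alone), with Crabp1 (3.28) and Sohlh1 (2.95). Of 27 genes of undifferentiated spermatogonia, 14 rose and 1 fell, over all genes and adjusted over the list alone, with Neurog3 (4.94), Lin28a (2.69) and Taf4b (1.28). Camera gave adjusted p-values of 2.75e-42, 5.84e-23, 5.84e-23 and 1.48e-06 for these lists. With an estimated correlation the first 3 passed (adjusted p = 0.0133, 0.0133 and 0.0134), and undifferentiated spermatogonia had an adjusted p = 0.110. With offsets as well, the same 3 passed on counts (adjusted p = 0.0134 for each) and none on log2 CPM (smallest adjusted p 0.0532).

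Lists of Leydig, stromal, endothelial and macrophage genes fell in the libraries labelled cKO, and that of Sertoli cells was not called. Of 12 Leydig cell genes, 7 fell (7 adjusted over the list alone), with Inhba (-2.03), Cyp11a1, the first enzyme of steroid synthesis (-1.95), Hsd3b1 (-1.43) and Scarb1 (-0.77), and Star fell by 0.84 (SE 0.22), which did not pass without P4 cKO library 3 (-0.74, adjusted p = 0.0601, range over alternatives 0.00187 to 0.511). Of 14 stromal genes, 10 fell (12 fell and 1 rose adjusted over the list alone), with Col3a1 (-1.60), Pdgfra (-1.55), Col1a2 (-1.53) and Des (-1.26). Of 10 endothelial genes, 9 fell (10 adjusted over the list alone), with Cdh5 (-1.48), Tie1 (-1.33), Pecam1 (-1.25) and Egfl7 (-1.06). Of 12 macrophage genes, 8 fell (10 adjusted over the list alone), with Lyz2 (-2.72), Fcgr3 (-1.31), C1qb (-1.19) and C1qa (-1.13). Ribosomal protein genes fell in 40 of 84 cases and rose in 4 (48 and 4 adjusted over the list alone), Rpl39 (-1.25) and Rpl10 (-1.11) against Rpl39l (2.26) and Rpl10l (2.17). With an estimated correlation none of these passed (adjusted p = 0.0849 for Leydig and endothelial genes, 0.218 for stromal, 0.316 for macrophage and 0.434 for ribosomal genes). The lists of Cajal body genes, retinoic acid response and histones rose by camera. Of 25 Cajal body genes, 9 rose (11 adjusted over the list alone), with Gemin4 (1.44), Gemin5 (1.31), Mettl16 (1.16) and Mepce (0.84) and an adjusted p = 0.0849 with an estimated correlation. Of 18 retinoic acid response genes, 7 rose and 1 fell (8 and 2 adjusted over the list alone), with Rec8 (2.53) and Rbp4 (1.87) and an adjusted p = 0.0849 with an estimated correlation. Of 51 histone genes, 10 rose (8 adjusted over the list alone), with H1f1 (5.40), H2bc11 (3.68), H2ac13 (2.89) and Hist1h2al (72.7-fold higher at the floor, with no read at P4) and an adjusted p = 0.787 with an estimated correlation. Hist1h2al was read at 3.52 and 2.53 CPM in P7 cKO samples 2 and 3, and at 0 in sample 1. Sample 1 was highest for H1f1 (11.7 CPM against 1.86 and 1.90), H2bc11 (9.60 against 1.26 and 0.778) and H2ac13 (3.16 against 1.51 and 0.656).

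The highest single genes under the naming rule in the libraries labelled cKO were the transcription factor genes Sox3 (5.69, SE 0.31), Dmrtb1 (5.34, SE 0.44), Neurog3, Lhx8 (4.88), Nkx1-1 (4.55) and Tbx22 (4.54), then Tmem63c (4.28), Zfp936 (4.20), Grik3 (3.96) and Sall1 (3.93). The lowest were Pnmt (-5.53, SE 0.34), the opioid precursor Pdyn (-4.80), Gpnmb (-4.80), Ccl17 (-4.35), Cbln1 (-3.75), Klkb1 (-3.58), Cnga1 (-3.43), Ftcd (-3.38), Gldn (-3.31) and Ndnf (-3.27). Lsm7 (-0.60, adjusted p = 0.107) did not pass, but its fall did with length and GC offsets (-0.68, adjusted p = 0.0156) and without P7 cKO library 1 (-1.001, adjusted p = 0.00117), in a range over alternatives from 0.00117 to 0.289. Gfra1 (0.16), Id4 (-0.06), Sox9 (0.20), Cdkn1a (-0.21) and Mdm2 (0.07) did not pass. In all 2663 genes rose and 2709 fell by edgeR's test, and 5866 passed with offsets, 5277 of them shared. The count was 3520 without P4 cKO library 2 and 3571 without P4 cKO library 3. With library totals as the scale, which put the median of all genes at 0.18 against 0.00, 3907 rose and 1818 fell. Not called in cKO were the lists of Sertoli cells (median -0.05, or 0.13 with library totals), LSm proteins (0.09), the core spliceosome (0.05), the minor spliceosome (0.19), snoRNA hosts (-0.32), messenger RNA decay (0.14), p53 targets (0.05), the cell cycle (0.05), stress response (-0.06, or 0.12), interferon response (-0.09, or 0.09) and snoRNA genes (0.14). With offsets the retinoic acid list passed on counts (adjusted p = 0.00347, or 0.0862 with an estimated correlation) and not on log2 CPM (0.125, or 0.0939 without offsets). The snoRNA hosts passed on both (0.0330 and 0.0114), with an adjusted p of 0.827 without and 0.547 with offsets at an estimated correlation. The erythroid and scaRNA lists had medians of -4.36 and 1.21, untested.

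How far the course in WT was seen in the libraries labelled cKO was asked across genes. Of 4016 genes called in WT and 5372 called in cKO, 993 rose in both (315.0 by chance) and 883 fell in both (270.2 by chance), while 50 went in opposite directions. Stra8, Kit, Zbtb16, Dazl and Neurog3 were among those that rose in both, and Pnmt, Ccl17 and Pdyn among those that fell in both. Pearson's r of the log2 fold changes was 0.382 over all genes, 0.647 over genes called in WT and 0.716 over genes called in cKO. The slope of cKO on WT was 0.371 over genes called in WT, a set whose WT values are raised by their selection.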

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

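Of the tests in this part, those of GC content and gene length, library batch and genotype at P7 were chosen after the result was seen. Among 106 named genes of the genotype comparisons, 8 had every sample labelled cKO on one side of WT at P4 and on the opposite side at P7. The difference between the stages did not pass edgeR's interaction test for any of them (adjusted p from 0.0626 to 0.0865), nor with limma-voom or with length and GC offsets. It passed for 8 of 8 with DESeq2 (highest adjusted p 0.0230), for 5 in edgeR without a filter, and for 7 without P7 cKO library 1, so it rested on the setting. With 1 WT sample at P7, chance alone puts all 3 others on a given side in 25% of genes. The interaction (log2) was 4.09 for Dscaml1, 1.46 for Tdrd9, 3.57 for Mylk2, -1.88 for Sox9, -1.28 for Aard, -1.87 for Fdx1, -1.59 for Star and -2.49 for Lyz2. Sox9 was read at 32.5 and 51.9 CPM in P4 WT, 84.9 to 94.4 CPM in P4 cKO, 178.1 CPM in P7 WT and 90.5 to 107.5 CPM in P7 cKO. With length and GC offsets, the P7 values were 0.00 for Fdx1 and 0.02 for Star.

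The 3129 genes called between the genotypes at P7 could stem from the P7 WT libraries rather than from the genotype. With length and GC offsets, 2 genes passed, and the median absolute log2 fold change of the calls went from 1.08 to 0.40, which fits a GC and length trend as the main source. A separate preparation of the P7 WT libraries may go with that trend: their spermatid transcripts, from a list of 20 genes of cells that a testis of this age should lack, reached at most 9.56 RPM (reads per library scaled to 1 M) against at least 19.6 in the other libraries. The cut-off for this test, written after the data were seen, was under 0.1 of the other libraries. It was not met, although 9 of the 20 genes, Prm1, Prm2 and Tnp2 among them, had no read in either P7 WT library and reads in each of the other 8. A genotype effect that is alike at both stages was taken to give a high correlation of the corrected P4 and P7 fold changes. That correlation was 0.0779, under the cut-off of 0.5 written after the data were seen. Noise in the fold changes also lowers such a correlation (median SE over genes, without offsets, 0.257 at P4 and 0.323 at P7). The value that a shared effect would give was not estimated, so this test cannot decide. An effect alike at both stages and an effect of P7 alone both stay possible. As the P7 WT group is 1 sample, batch and genotype cannot be told apart at P7.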

How the results depend on the processing

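The 10-library fit was the design fixed beforehand and became an alternative after the data were seen. Chosen after seeing the data were the length and GC offsets with all tests that use them, and the fit without the P7 WT libraries. So were the correlations limited to genes with an average log2 CPM of 1 or more. The other alternatives were fixed before. Where a value changed and nothing else is said, the cause was not tested. Of 5561 values of named genes under the alternatives, Lsm7 included, 5023 kept direction and side of the threshold, 436 lost the call, 66 gained it and 36 changed sign. Genes changed at P4 (1651) numbered 3008 with DESeq2, 3229 in a fit of the compared libraries alone, 2895 with 10 libraries, 570 with offsets and 760 at an absolute log2 fold change of at least 1. At P7 (3129) they numbered 0 in a fit of the compared libraries alone (DESeq2 over all samples 4247, limma-voom 3495), 6905 with 10 libraries, 2 with offsets and 1917 at the fold threshold. Between the stages, WT (4016) gave 7279 with 10 libraries, and cKO (5372) gave 2877 at the fold threshold. The interaction (0) gave 3 with library totals, 431 without a filter, 1665 with DESeq2 and 3105 with 10 libraries. The 10-library fit takes the near-identical P7 WT libraries as separate samples. Without the P7 WT libraries P4 gave 1728 and the cKO course 5445.

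Leaving out 1 library gave 2 to 4157 genes at P4, 961 to 4921 at P7, 1187 to 6315 between stages in WT, 3520 to 5569 in cKO and 0 to 1455 for the interaction. In each case the highest count of genes came without P7 cKO library 1, which differed most from its group. Called lists for the interaction ran from 0 to 4, and were 3 with library totals. With an estimated correlation, 0 lists were called at P4 (fry 8), 0 at P7 (fry 4), 2 in WT and 3 in cKO between stages.

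No clear pairing by replicate number was seen: correlations of same-numbered deviations ran from -0.19 to 0.17 over 9 pairs, with 2 over 0.1. Pairs that include the P7 WT libraries could show little, as those libraries differ by about the sampling noise. The remaining pairs are too few to exclude a pairing by replicate number. With the number as a block, 2732 genes were called at P4, 7438 at P7, 7812 in WT, 4311 for the interaction, and 2 lists for the interaction; Zbtb16 at P4 was 0.0435 and Stra8 at P7 was 0.14. With the block within stage, 500, 6025, 761 (cKO course) and 1175 (interaction) were called, and Lsm7 was 0.0644 at P7 and -0.76 in the WT course, Stra8 at P7 0.0722, Cdkn1a 0.23 in WT and 0.29 in cKO, and Mdm2 in cKO -0.0206. The interaction of Sox9 and Star passed with both blocks (adjusted p 0.00258 and 0.00362 over all groups, 0.0229 and 0.0280 within stage), as did the fall of Lsm7 in the cKO course with the first (0.0218). These fits took the P7 WT libraries apart.

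The P4 to P7 correlation of genotype effects (-0.00) was 0.131 by Spearman, 0.189 with the stricter filter, 0.0628 with 10 libraries, -0.122 with offsets and -0.0328 to 0.109 without 1 library. The correlation of the courses (0.382) was 0.247 without a filter, 0.553 with the stricter filter, 0.448 with 10 libraries and 0.333 to 0.439 without 1 library.

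Signs turned in genes that had not passed. Stra8 at P7 was 0.10 with library totals, 0.0247 with the stricter filter, 0.0137 with 10 libraries and -0.24 to 0.11 without 1 library. Zbtb16 at P4 was 0.0101 with limma-voom and -0.37 to 0.41 without 1 library. Id4 was 0.12 with library totals in the cKO course. With offsets Id4 was 0.45, Ddx4 0.10, Sycp3 0.0471, Star 0.0198 and Cdkn1a -0.13 at P7, Cdkn1a 0.23 in the WT course and Id4 6.11e-04 in the cKO course. Without 1 library, Lsm7 ran from 0.36 to 0.85 at P4, from -0.53 to 0.10 at P7 and from -0.12 to 0.36 in the WT course. In the WT course Cdkn1a ran from -0.28 to 0.13, Gfra1 from -0.24 to 0.59 and Id4 from -0.39 to 0.0258. In the cKO course Gfra1 ran from -0.0151 to 0.45 and Id4 from -0.21 to 0.0544, and Dazl at P4 from -0.84 to 0.19. A log2 fold change of 1 was recovered for 9 of 100 simulated genes at P7, in a simulation where 200 genes changed.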

Other observations

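Of the tests in this part, those of germ cell share (both reference lists), of GC content for the meiotic list and of swapped or exchanged labels were chosen after the result was seen. The covariance test and the test of Lsm7 with offsets were written before their results, but rest on offsets chosen after the data were seen. Some genes without an assigned function, outside the naming rule and chosen after their values were seen, parted the groups. Gm8615 (chromosome 5, 149154128 to 149156192) was read at 42.4 ± 3.69 CPM in P4 WT (SD, n = 2) and 39.6 CPM in P7 WT, against 0.295 ± 0.197 (SD, n = 3) and 0.619 ± 0.517 CPM (SD, n = 3) in the libraries labelled cKO. The log2 fold change was -7.15 at P4 (edgeR adjusted p = 0.00163) and -6.04 at P7 (adjusted p = 0.00642). 4930413G21Rik was read at 2.90 CPM in P4 WT and 1.99 CPM in P7 WT against 24.3 and 17.7 CPM. AI506816 was read at 32.5 ± 2.63 CPM (SD, n = 3) in P4 cKO and at 0.173, 0.590 and 0.410 CPM in P4 WT, P7 WT and P7 cKO. Each of the 3 kept its side in all samples of the groups named.

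Transcripts of organs or cells beside the testis also differed between libraries. The epididymal gene Gpx5 had 550 and 596 reads in the P7 WT libraries and 12 to 122 in the other 8, and Adam7 had 216 and 214 against 4 to 52. In a list of 11 epididymal genes, written after the libraries were first examined, the sum was 65.1 and 65.2 RPM in P7 WT against 24.4 to 57.9 RPM elsewhere, and Cst8 gave most of the reads in the other libraries. Rn45s took 0.143% of reads in each P7 WT library and at least 0.347% in the P7 libraries labelled cKO. Alas2 was read at 14.9 CPM in P7 WT and at 2.19 to 10.8 CPM in the other samples.

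The meiotic and pan-germ-cell lists were lower at P4 in the libraries labelled cKO at the preset correlation, but did not pass with an estimated one (adjusted p = 0.235 and 0.394, or 0.349 and 0.612 with offsets), and spermatid transcripts were lower as well (19.6 to 24.8 RPM against 27.3 and 36.2 in WT). If GC content and gene length were the source, the meiotic median (-0.68) would have shrunk to less than 0.5 of its size with offsets, and it stayed at -0.64 (95% bootstrap interval over genes -0.97 to -0.35). An earlier point of the P4 to P7 course would have given the P4 genotype change a negative covariance with the WT change between the stages. With length and GC offsets, the covariance was 0.0531 above that of simulated unchanged groups sharing the P4 WT samples (0.0960 against 0.0429). That outcome had been set as speaking against that source before this test was run, but after the offsets were chosen. The correlation lay below the simulated one (0.204 against 0.448). Of lists called at P4, the meiotic, Leydig cell and ribosomal medians (-0.68, 0.51 and 0.83) ran opposite to the WT course (1.41, -0.65 and -0.56). So did the pan-germ-cell, stromal, macrophage and stress response medians. The interferon (-0.69 and -0.51), histone (1.32 and 0.92), LSm (0.45 and 0.12), core spliceosome (0.39 and 0.04) and Sertoli cell medians (0.39 and 0.02) ran the same way. The WT medians of the Sertoli cell and core spliceosome lists lay near 0 and changed sign with library totals. Both changes subtract the same P4 WT samples, so noise in those pushes the medians of a list to the same sign. The lists could not decide, nor did the covariance over all genes, and this source stays open. A smaller share of germ cells would lower germ cell lists alike: the meiotic median lay -0.75 from that of undifferentiated spermatogonia (95% interval -1.33 to -0.33), which argues against a lower share as the whole source. As other testis cells also express some genes of that list, a second test was then run against the pan-germ-cell list and gave -0.28 (95% interval -0.78 to 0.03), so the outcome turned on the reference list and a smaller share stays possible, as do an effect of genotype and RNA of later germ cells from outside the sample, neither of which was tested apart from it.

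A lower Lsm7 level was not detected in the libraries labelled cKO. A swap of single libraries would place samples nearer to the other genotype, and 8 of 8 samples with a partner in their group correlated better with their own group. This says nothing of the P7 WT sample. For the P7 cKO samples it cannot decide, since their only counterpart was that sample, which its GC trend set apart. An exchange of whole groups would leave these correlations unchanged and stays open: with the P4 labels exchanged, the Lsm7 value would be -0.58 (SE 0.30), which did not pass. A GC and length trend could hide a decrease at P4, but the fold change with offsets was 0.25 (SE 0.20), above 0; at P7, outside that test, it was -1.02 (adjusted p = 0.141, range over alternatives 0.1196 to 0.983), so a decrease there stays possible. Lsm7 RNA from cells that keep the gene, or from exons outside the deletion, is a possible explanation that the table cannot exclude: pan-germ-cell genes had a median of 16.1 CPM in P4 WT, not under the 10 CPM foreseen, and no count per exon or cell type was used here.

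The change between the stages in the libraries labelled cKO called 5372 genes. Among the 10 splits of these 6 samples into 3 and 3, 1 gave as many genes, the real one, and the highest other gave 1; 10 splits are too few for a share under 0.05.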
